A study of Mus musculus with 26 samples.

How the data were processed

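Reduced representation bisulfite sequencing (RRBS), which reads cytosine methylation at fragments cut by MspI, had been applied to 26 mouse libraries in 13 groups of 2 biological duplicates. Embryonic stem cells (d0) and the cortical cells made from them after 12 and 21 days of culture (d12 and d21) came from 3 lines. BJ1 has a C57BL/6J mother and a JF1 father, JB6 has a JF1 mother and a C57BL/6J father, and E14 is an inbred line. The in vivo libraries were BJ1 and JB6 dorsal telencephalon at E13.5 and cortex at P0. Per the labels' protocols, E14 and the hybrid lines were kept in different stem cell media and plated on different coatings, so any difference between E14 and the hybrids includes those conditions.

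Per the submitters' processing notes, reads were handled with bcl2fastq 2.17, FastQC, Trim Galore and Bismark 0.14.3 on genome build mm9. The deposited coverage files give for each cytosine position the percent of calls that were methylated, as the authors computed it, and this percent was checked to equal the share of the methylated count on every line. The deposited counts of methylated and unmethylated calls per position are raw and carry no normalization, and they entered every test here. Each hybrid library has 3 files, with all reads, reads assigned to JF1 and reads assigned to C57BL/6J, per the file names, and the assignment itself was made by the authors. E14 libraries have only the file with all reads, so E14 gives no value per parental allele.

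Depth ranged from 64493093 methylation calls in d21 BJ1 replicate 1 to 143887212 in P0 BJ1 replicate 1, and 81.3% to 97.4% of the calls of a library lay at positions with at least 10 reads. Reads assigned to C57BL/6J gave 7817993 to 18113885 calls per hybrid library and reads assigned to JF1 gave 7968988 to 18189482. The mitochondrial genome read as methylated in 0.0261% to 0.532% of calls, which bounds unconverted cytosines. Intervals are exact Clopper-Pearson 95% intervals and cover counting error only, since the reads carry no molecular identifiers.

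Counts were summed over tiles of 500 bp with at least 3 positions of at least 10 reads in every sample of a comparison, on the 19 autosomes. Each tile was tested by logistic regression on the summed counts with 0.5 added to each. The F test used the Pearson overdispersion moderated across tiles as limma's squeezeVar does, computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Line or cross was a covariate, except in E14 against the hybrids, where cross was not fitted, and p-values were adjusted by Benjamini-Hochberg. A tile was called at an adjusted p below 0.05 and a difference of at least 20 percentage points between group means. Only the groups compared entered a fit. The mean methylation level of a sample is the mean over 112565 tiles covered in all 26 samples, compared by a two-sided exact permutation test with labels permuted within line, or among all samples of the stage for E14 against the hybrids. The p-values measure the spread between these duplicates, except those of the lists of tiles described below. Where tile or region fits pooled lines or crosses, the error also holds the difference between them in the change. In E14 against the hybrids it also holds the distance between BJ1 and JB6.

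The allele-specific counts of hybrids were tested in tiles with at least 10 calls on each allele in every sample, by a logistic model with terms for sample, parent and strain of the allele. A tile was called at an adjusted p below 0.05, at least 30 percentage points between alleles, and the same sign in both crosses. The 33 windows around known imprinted regions, the Hox clusters A to D and the protocadherin clusters were fixed by position before the data were examined. So were the tests, the thresholds and the alternatives listed as planned. The imprinted windows are of germline regions, except Zdbf2, Nesp, Ndn, Magel2, Peg12, Igf2, Cdkn1c, Meg3, Dlk1 and Igf2r, which are somatic regions and not imprinting control regions. The window of H19 holds the germline region together with the H19 promoter. Within a window, the parental levels come from the tiles in which both crosses in vivo had the stated parent's allele higher by at least 30 percentage points. Because the in vivo samples chose these tiles, their levels set the reference and are not independent evidence of imprinting. Levels over both alleles use window tiles between 30% and 70% in every in vivo sample, a rule added after values were seen. A list of tiles was set against 10000 random lists of the same size matched on the mean methylation level. Its p-value measures the spread among tiles and not between samples. Neighbouring tiles of a cluster were set against tiles drawn singly, so this p-value may be too small.

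Named regions follow a rule fixed beforehand. It names every imprinted window and, with no gene annotation of the build of the files, the 5 tiles with the largest increase and the 5 with the largest decrease in each comparison among called tiles of the same sign in every line or cross. The text gives the first of each direction for d12 vs d0, P0 vs E13.5 and d21 vs P0 and the first decrease for d21 vs d12, a choice made after values were seen. It also names the regions of parent-of-origin tiles outside the windows. The reference gene table is of assembly GRCm38.p6, so its coordinates were not used and tiles carry no gene names. Promoter changes of the gene lists were not computed for the same reason.

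The alternatives were coverage minimums of 5 and 20 reads, tiles of 1000 bp, difference thresholds of 10 and 30 percentage points, positions of very high coverage left out, edgeR 4.0.16 (quasi-likelihood test, R 4.3.3, with a common dispersion estimated on a subset of the tiles), a moderated t test on log2 ratios written in Python after limma (called limma in the text; limma 3.58.1 itself was loaded only by edgeR), a replicate block, and each replicate left out in turn. The duplicates of different groups share only a number. The procedure was tested on simulated data after the first fits of the real files had been made, with 200 tiles changed among tiles that kept the real coverage. Except for the parent term, tiles were changed by 20, 40 or 60 points. Recovery at 20 points, the size of the call threshold, is not given. For d21 vs d0, the logistic test recovered 98.5% of tiles changed by 40 points and 100% of those changed by 60 points among 116185 tiles. For d21 vs P0 it recovered 56.7% and 93.9% among 144652 tiles. For E14 vs hybrid at d21 it recovered 2.99% and 31.8% among 118946 tiles, and limma 8.96% and 81.8%. The parent term at d21 recovered 13% of tiles with a parental difference of 40 points and 74% of those with 80 points among 56939 tiles, and 92% and 100% among 62202 tiles in vivo. None of these simulations gave a false call, a count of 0. In them all lines had the same level and the same change in a tile, the extra spread was fixed, and few tiles changed. The real lines parted and many tiles changed, so these rates need not hold for the real comparisons.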

Results

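DNA methylation was measured by RRBS in 26 mouse libraries to compare cortex grown from embryonic stem cells with cortex of the embryo and newborn, over the whole genome and on each parental allele. The cultures were hybrid BJ1, hybrid JB6 and inbred E14 cells at d0, d12 and d21, and the in vivo tissues were BJ1 and JB6 dorsal telencephalon at E13.5 and cortex at P0, with 2 duplicates in each of 13 groups. Libraries held between 64493093 and 143887212 methylation calls. Duplicates correlated at 0.968 to 0.996 over tiles of 500 bp. Coordinates are of build mm9.

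Stem cells of the 3 lines had similar mean methylation levels, and the lines parted as they differentiated. At d0 the mean level was 50.3% ± 1.08 in BJ1, 49.0% ± 3.8 in JB6 and 45.1% ± 1.03 in E14 (SD, n = 2 each). At d12 it was 55.1% ± 0.597 in BJ1, 62.2% ± 0.345 in JB6 and 67.5% ± 0.830 in E14. At d21 BJ1 stood at 47.4% ± 1.78, JB6 at 62.6% ± 1.99 and E14 at 66.4% ± 1.08. The tissues lay close together, at 56.0% ± 0.398 at E13.5 and 54.8% ± 0.279 at P0 (n = 4 each).

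**Figure D1:**
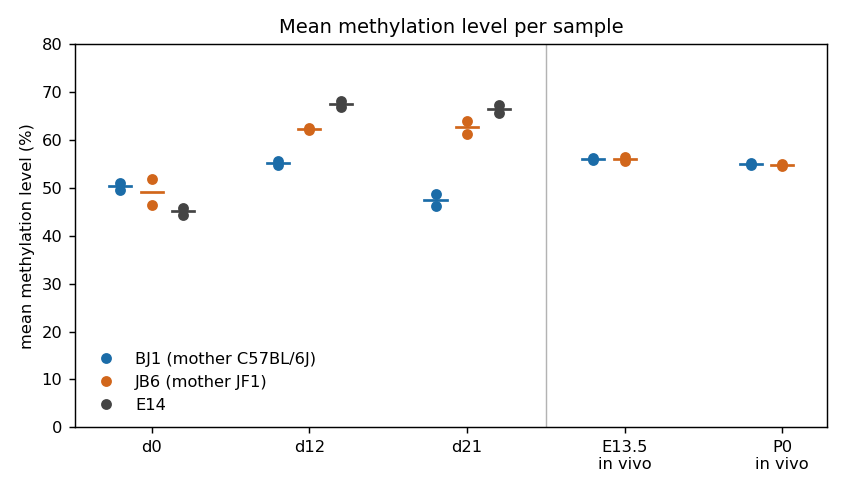
Mean methylation level in percent over 112565 autosomal tiles for each library, with a point per library and a bar at each group mean, by stage and line. E14 and JB6 cultures at d12 and d21 sit above the tissues, while BJ1 at d21 falls to 47.4%.

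Differentiation to d12 raised the mean level by 13.47 percentage points over d0, from 48.1% to 61.6%, with a rise of 4.80 points in BJ1, 13.2 in JB6 and 22.4 in E14. The two-sided exact permutation p was 0.00926, the smallest that the 216 labellings allow. From d0 to d21 the change was 10.7 points (exact p 0.0556, but 0.0463 without d0 BJ1 replicate 1, d0 BJ1 replicate 2 or d21 BJ1 replicate 1), with BJ1 at -2.86, JB6 at 13.54 and E14 at 21.3. Over cytosine positions in place of tiles the exact p was also below 0.05. From d12 to d21 the change was -2.79 points (exact p 0.111, but 0.0278 without d21 JB6 replicate 2 and 0.00926 with each sample's own tiles), with -7.66 in BJ1, 0.348 in JB6 and -1.07 in E14. Cortex at P0 lay 1.15 points below E13.5, a change of -1.15 with an exact p of 0.0556, the smallest that 36 labellings allow. Hybrid d12 cultures differed from E13.5 by 2.68 points (exact p 0.333), and hybrid d21 cultures from P0 by 0.172 points (exact p 0.833), where BJ1 lay at -7.53 and JB6 at 7.88. E14 differed from the hybrids by -4.57 points at d0 and 11.4 points at d21 (exact p 0.133 at each, where 15 labellings allow no p below 0.0667). None of these 8 comparisons was adjusted for the others.

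The question of which loci change as stem cells become cortical cells was asked tile by tile. At d12, tiles gained methylation far more often than they lost it. Tiles between 20% and 80% at d0 gained in 36.9% of cases and tiles below 20% in 17.6%, while tiles with at least 20 cytosine positions gained in 9.54%. Of 133263 tiles tested, 32368 were higher and 303 lower than at d0. The first tile by increase, on chromosome 10 from 79858001 to 79858500, rose from 3.77% ± 2.90 to 94.8% ± 3.66 (n = 6 each, adjusted p 1.01e-09). The first by decrease, on chromosome 8 from 63762501 to 63763000, fell from 79.3% ± 3.92 to 8.47% ± 3.17 (adjusted p 1.15e-08).

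At d21 BJ1 shared many of the gains of the other lines and lost methylation at many other loci. Across lines, 23936 of 116185 tiles were higher than at d0 and 657 lower. Of these 24593 tiles, 23176 rose by at least 20 points in E14, 22953 in JB6 and 14113 in BJ1. Each line entered the fit that called these tiles, which favours tiles where all lines rose. Fitted alone, E14 had 71381 tiles higher and 415 lower, JB6 had 35050 higher and 660 lower, and BJ1 had 20044 higher and 39263 lower (n = 2 against 2 in each line). A test of the difference itself, the interaction of stage and cross, called 52196 of 145197 tiles, of which 52072 rose more in JB6 than in BJ1. This test was added after values were seen. It called 25580 tiles without d0 BJ1 replicate 1 and 29167 without d21 JB6 replicate 2. The interaction of stage and E14 called 37515 tiles, of which 37187 rose more in E14 than in the hybrids, and the count rests on single libraries and on the model. With a replicate block it was 0 by the logistic test, with 47273 tiles at an unadjusted p below 0.05, and limma without the block called 43733. It was 48 without d21 E14 replicate 2, 1421 without d0 E14 replicate 2, 9826 without d21 E14 replicate 1, 13508 without d21 BJ1 replicate 2 and 23565 without d0 BJ1 replicate 2. The E14 libraries of d0 also had 1.14 times the share of reads on chromosome 14 and 1.33 times that on chromosome X of the later E14 libraries, so a change of the cells other than differentiation is not separated from the E14 changes since d0.

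Between d12 and d21 few tiles changed in all lines together, with 7 higher and 294 lower of 115226, and 522 called without d21 JB6 replicate 2. BJ1 alone lost methylation in 7835 tiles and gained it in 44, E14 alone lost it in 1 and gained it in 0, and JB6 alone had 0 calls by the logistic test, with 7874 tiles at an unadjusted p below 0.05. The first tile by decrease across lines, on chromosome 8 from 128082501 to 128083000, fell from 61.3% ± 6.59 to 21.0% ± 7.54 (n = 6 each, adjusted p 0.000896). BJ1 and JB6 did not differ in stem cells or tissues to this extent. JB6 lay above BJ1 in 7656 tiles at d12 and 60117 at d21, against 0 calls at d0, 4 at E13.5 and 8 at P0. By limma the counts of calls were 0 at d12, 62014 at d21, 13 at d0 and 0 in each tissue, and tiles at an unadjusted p below 0.05 by the logistic test numbered 4429 at d0, 7640 at E13.5 and 9874 at P0.

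In the embryo, maturation from dorsal telencephalon to newborn cortex was mostly a loss of methylation. Of 161296 tiles, 3927 were lower at P0 than at E13.5 and 64 higher, and tiles between 20% and 80% at E13.5 lost most often, in 7.51% of cases. The first by decrease, on chromosome 9 from 41254001 to 41254500, fell from 91.8% ± 2.61 to 23.7% ± 7.99 (n = 4 each, adjusted p 6.48e-08). The first by increase, on chromosome 18 from 36444001 to 36444500, rose from 10.1% ± 1.85 to 55.8% ± 6.18 (adjusted p 8.71e-09).

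Cultured hybrid cells were then set against the tissue of the corresponding stage. Of 155666 tiles, 19114 were higher than at E13.5 and 2557 lower, and the gains came to 23% of tiles below 20% at E13.5 and 27.3% of tiles between 20% and 80%. At d21, 18601 of 144652 tiles were higher than at P0 and 15134 lower. The gains came to 24.4% of tiles below 20% at P0 and 24.6% of tiles between 20% and 80%, and the losses to 20.4% of tiles above 80% and 3.14% of tiles between. The losses were those of BJ1, with 57457 tiles lower and 16825 higher when fitted alone, against 609 lower and 25782 higher in JB6. With a threshold of 10 percentage points the balance turned, to 25182 higher and 41664 lower. The first tile by increase at d21, on chromosome 15 from 75834501 to 75835000, stood at 93.0% ± 2.96 against 5.15% ± 0.782 at P0 (n = 4 each, adjusted p 5.68e-07). The first by decrease, on chromosome 11 from 46322001 to 46322500, stood at 24.5% ± 3.16 against 93.5% ± 1.88 (adjusted p 4.12e-06). Cultures and tissues differ in cell source, handling and cell mixture together, and these cannot be separated here.

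The Hox clusters were nearly unmethylated in cortex and carried methylation in cultures at every stage. HoxA tiles averaged 17.2% ± 1.55 at d21 against 1.80% ± 0.154 at P0, HoxB 21.0% ± 2.47 against 6.48% ± 0.0592, HoxC 17.5% ± 2.12 against 2.21% ± 0.195 and HoxD 19.7% ± 2.14 against 2.38% ± 0.0819 (n = 4 each). Called higher were 19 of 78 HoxA, 27 of 86 HoxB, 18 of 61 HoxC and 21 of 60 HoxD tiles, with 0 called lower, while 24.4% of all tiles below 20% at P0 were called higher. At d0 the HoxA tiles compared with d21 already averaged 12.1% ± 1.09 (n = 6), so these levels were present in stem cells. Against random lists matched on methylation, the rise over P0 was at the 99.89th percentile for HoxD (adjusted p 0.00587 over the 8 lists) and the 98.97th for HoxC (adjusted p 0.0333), but at the 86.62nd for HoxA (adjusted p 0.306) and the 60.2nd for HoxB (adjusted p 0.796). From d0 to d21 the median change was smaller than in matched lists, at 1.10 points for HoxD where these gave 7.12 (adjusted p 0.000400) and 2.37 for HoxA where these gave 5.22 (adjusted p 0.0134). HoxB and HoxC lay below every matched list. Tiles called higher and lower were 3 and 0 in HoxA, 1 and 2 in HoxB, 0 and 4 in HoxC and 1 and 3 in HoxD. The HoxC mean was 17.7% at d0 and 17.6% at d21. From d0 to d12 all 4 medians also lay below matched lists (adjusted p 0.000320 each), with the HoxC mean at 16.6% at d0 and 16.4% at d12.

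The gamma protocadherin cluster gained methylation on differentiation in every line. Its tiles went from 23.6% ± 1.59 at d0 to 60.3% ± 4.41 at d12 (n = 6 each), with 52 of 59 tiles higher, and a median change of 38.2 points against 21.8 points in matched lists (adjusted p 0.000320). At d21 the hybrids stood at 58.6% ± 9.24 and P0 cortex at 35.8% ± 0.426 (n = 4 each), with 36 of 64 tiles higher, a median change of 23.4 points against 16.3 in matched lists (adjusted p 0.0517, and 0.312 for d12 against E13.5). The alpha cluster rose to d12 as matched lists did, by a median of 18.6 points against 17.6 (adjusted p 0.833). At d21 it averaged 37.6% ± 11.8 in hybrids against 45.4% ± 1.03 at P0, a median change of -12.8 points where matched lists gave 18.6 (adjusted p 0.000800). The lower level was that of BJ1, with 27.7% against 46.1% at P0, while JB6 had 47.6% against 44.8%. In the tiles compared between d0 and d21, BJ1 stood at 26.9% at d0 and 27.6% at d21. The beta cluster had a median change of -13.7 points from P0 where matched lists gave 1.68 (adjusted p 0.0124), with 43.0% in BJ1 against 71.03% at P0 and 70.1% in JB6 against 68.5%. These differences between crosses were not tested.

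Parental imprints were mapped in vivo from the reciprocal crosses. Of 62202 tiles, 36 differed by parent of origin, 26 with the maternal allele higher and 10 with the paternal allele higher. Joined, they formed 28 regions, of which 24 lay in 18 of the 33 imprinted windows. The windows of Mcts2, Nesp, Peg10, Ndn, Magel2, Rasgrf1, Plagl1 and Airn had no tile with enough calls on both alleles, so none could be called there. The maternal allele of Mest, from 30688001 to 30689500 on chromosome 6, was at 98.1% at P0 and the paternal allele at 0. The other 4 regions lay outside the windows. On chromosome 9 from 89780501 to 89781000, next to the window of Rasgrf1, the maternal allele lay at -59.4 points relative to the paternal, with -44.9 in BJ1 and -74.0 in JB6. On chromosome 12 from 110852501 to 110853000 the maternal allele was higher by 47.3 points. On chromosome 7 from 67637001 to 67637500 it was higher by 45.1 points, but by 23.2 in BJ1 and 66.9 in JB6, so the crosses differed. On chromosome 12 from 81269001 to 81270000 it was higher by 55.4 points, but by 15.0 in BJ1 and 95.7 in JB6, so parent and strain both entered.

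Of 33 in vivo parent-of-origin tiles that could be followed in cultures, 15 were called at d0, 12 at d12 and 13 at d21, and 0 were called with the opposite parent higher. Their median parental difference, signed by the in vivo direction, was 90.4 points in vivo, 61.2 at d0, 36.9 at d12 and 38.6 at d21. Counted over all tiles, 22 differed by parent at d0, 17 at d12 and 13 at d21. Limma on the differences between alleles called 0 at each of these stages, with 4499, 4712 and 4718 tiles at an unadjusted p below 0.05, and 36 in vivo. The d12 count was 11 without d12 BJ1 replicate 2 or d12 JB6 replicate 2, and the d21 count 8 without d21 BJ1 replicate 2 and 7 without d21 JB6 replicate 1.

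Whether cultured cortex keeps imprints was examined on each parental allele of the imprinted regions, with 14 to 1137 calls per allele and sample. At a group of maternal imprints the unmethylated allele stayed near 0 at d21. The paternal allele of Kcnq1ot1 stood at 2.18% ± 2.74, of Peg3 at 0.0749% ± 0.150, of Snrpn at 0.872% ± 1.16, of Impact at 0.823% ± 1.65 and of Zrsr1 at 1.58% ± 0.636 (SD, n = 4 each), against at most 0.375% at P0. The rise over P0 was called at Zrsr1 (1.21 points, adjusted p 0.0118), Snrpn (0.819 points, adjusted p 0.0180) and Impact (0.774 points, adjusted p 0.0310), and not at Kcnq1ot1 (adjusted p 0.0714) or Peg3 (adjusted p 0.478), while limma called none of the 5. Snrpn and Impact were not called without d21 BJ1 replicate 2 (0.286 and -0.0391 points), P0 BJ1 replicate 1 (0.735 and 0.658) or P0 BJ1 replicate 2 (0.651 and 0.580), and Kcnq1ot1 was called without P0 BJ1 replicate 2 (2.32 points). Their maternal alleles remained methylated, at 94.2% ± 3.74 for Kcnq1ot1, 91.1% ± 4.92 for Peg3, 90.5% ± 6.06 for Impact, 78.0% ± 11.6 for Zrsr1 and 67.7% ± 26.5 for Snrpn. At Snrpn the maternal allele had 44.8% in BJ1 and 90.6% in JB6 at d21, and 49.6% and 84.7% at d0, so this difference was present in the stem cells.

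Other imprinted regions carried methylation at d21 on the allele that is unmethylated in cortex, in part already at d0. The maternal allele of H19 stood at 62.7% ± 6.37 at d21 against 7.86% ± 4.70 at P0, that of Zdbf2 at 54.8% ± 9.21 against 2.20% ± 0.731, and that of Cdkn1c at 70.5% ± 7.25 against 19.9% ± 2.43. The paternal allele of Cdh15 stood at 82.7% ± 15.3 against 15.8% ± 9.46, that of Mest at 43.7% ± 10.9 against 5.01% ± 4.27, that of Grb10 at 33.6% ± 11.3 against 1.11% ± 2.22, that of Nnat at 21.8% ± 13.4 against 0.359% ± 0.518 and that of Inpp5f at 17.7% ± 19.0 against 0.0644% ± 0.129. At Inpp5f and on the maternal allele of Meg3 the gain was that of BJ1, with 32.4% against 3.05% in JB6 at Inpp5f and 39.1% against 1.92% at Meg3, a difference that was not tested. At d0 the same allele stood at 44.2% for Zdbf2, 31.0% for H19 and 17.9% for Mest, and at most 6.30% for Grb10, Nnat and Inpp5f. Cdh15 was methylated on both alleles already at d0, at 86.1% and 85.3%. Cdkn1c had no parental difference at d0, with 33.4% and 34.4%. Of the regions named here, Zdbf2, Cdkn1c and Meg3 are somatic and the others germline. The H19 window also holds the H19 promoter, so its levels may not be those of the germline region alone.

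Over 17 regions testable in both, the normally unmethylated allele was higher at d21 than at P0 in 15, of which 11 rose by at least 10 points, and lower in 0, and in the remaining 2 it was not called, while limma on percentages called 8 higher (logistic regression moderated as in limma, adjusted p 9.73e-06 for Zdbf2, 2.68e-05 for H19, 0.000690 for Cdh15). The normally methylated allele was lower in 10, with a change of -28.9 points at Snrpn, -26.0 at Peg12 and -17.8 at Zrsr1, and higher in 1, Cdh15. At these 3 regions the difference from P0 was mainly that of BJ1, with 44.8% at d21 against 97.0% at P0 at Snrpn, 6.64% against 42.4% at Peg12 and 68.1% against 95.8% at Zrsr1. JB6 had 90.6% against 96.2%, 22.4% against 38.6% and 87.9% against 95.9%. At Grb10 (80.5% against 87.7%) and Impact (86.4% against 94.7%) JB6 was lower than BJ1 at d21. These differences between crosses were not tested. At Snrpn, Peg12 and Zrsr1 the mean of the normally methylated allele over both crosses did not fall from d0 to d21. It was 67.2% at d0 and 67.7% at d21 at Snrpn, 1.07% and 14.5% at Peg12 and 65.9% and 78.0% at Zrsr1. In BJ1 it was 49.6% and 44.8% at Snrpn, 2.14% and 6.64% at Peg12 and 53.9% and 68.1% at Zrsr1. The d0 cells, themselves cultured, already lay below P0, so a loss in culture before d0 is not excluded. The change from d0 to d21 was not tested. At d12 against E13.5 the normally unmethylated allele was higher in 11 and lower in 0, and the normally methylated allele was lower in 5 and higher in 1. For the normally methylated allele limma on percentages called 0 lower and 0 higher at d12, where 8 regions had an unadjusted p below 0.05 by the logistic test, and 6 lower at d21, as did the replicate block. The in vivo samples chose the tiles, which favours a lower methylated allele and a higher other allele in cultures. Over all covered positions of the windows the normally methylated allele was lower in 6 and higher in 2 at d21. The count of 10 became 4 without d21 BJ1 replicate 2, 5 without d21 BJ1 replicate 1 or P0 JB6 replicate 1, and 6 without P0 BJ1 replicate 1, P0 BJ1 replicate 2 or P0 JB6 replicate 2. The count of 5 became 3 without E13.5 BJ1 replicate 1 and 2 without d12 BJ1 replicate 1, d12 BJ1 replicate 2, E13.5 BJ1 replicate 2, E13.5 JB6 replicate 1 or E13.5 JB6 replicate 2, and the count of 1 at d12 became 0 without d12 BJ1 replicate 1, d12 BJ1 replicate 2 or E13.5 JB6 replicate 1. Over both alleles, all covered tiles of the imprinted windows lay a median of 3.49 points higher at d21 than at P0 where lists matched on that level gave 18.1, and 5.92 points higher at d12 than at E13.5 where they gave 20.9 (adjusted p 0.000800 each). Nap1l5 passed the coverage minimum in 2 samples per culture stage and was not tested.

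**Figure D2:**
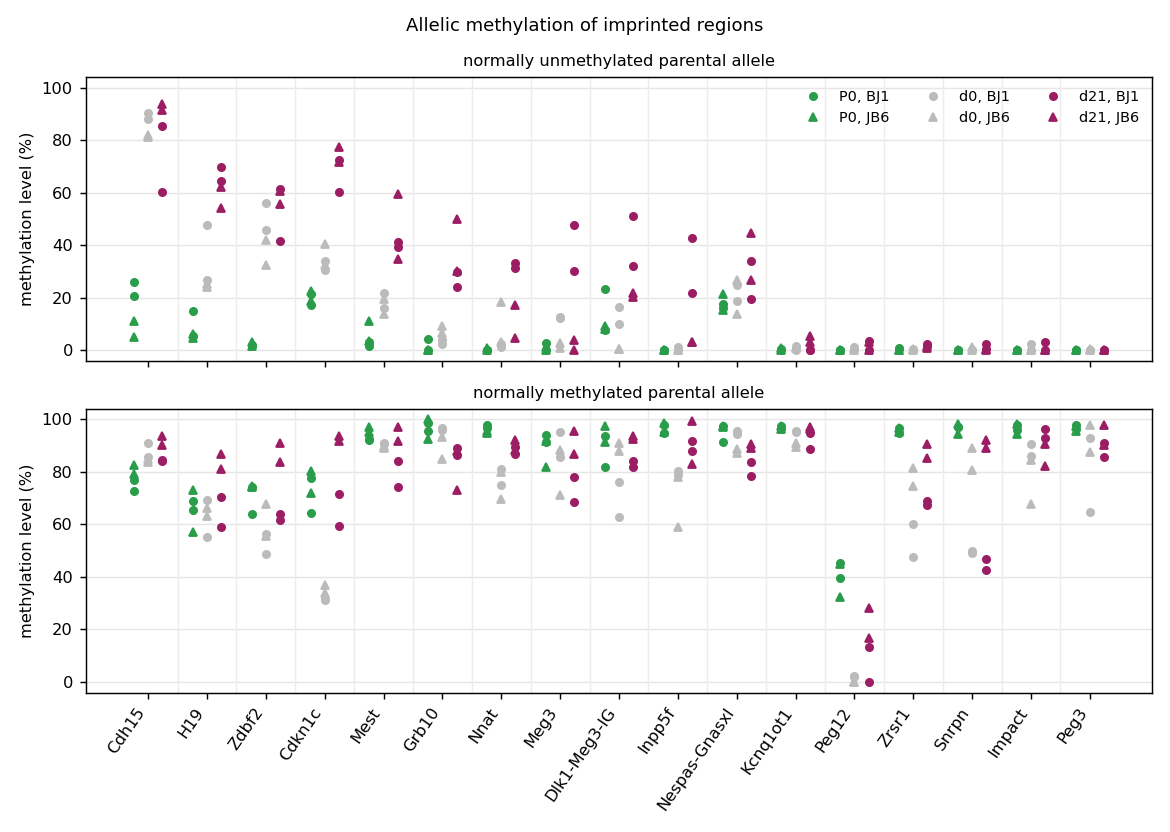
Methylation level in percent of the normally unmethylated allele (top) and the normally methylated allele (bottom) at 17 imprinted regions, with a point per library of P0 cortex, d0 and d21 hybrid cells, circles for BJ1 and triangles for JB6. Cdh15, H19, Zdbf2 and Cdkn1c are highest on the top panel at d21, and Kcnq1ot1, Peg12, Zrsr1, Snrpn, Impact and Peg3 stay near 0.

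Strain of origin marked many more tiles than parent of origin. In vivo, 1033 of 62202 tiles differed between the C57BL/6J and JF1 alleles in both crosses, with C57BL/6J higher in 594 and JF1 higher in 439. Hybrid stem cells had 1411 such tiles, d12 cultures 458 and d21 cultures 374. By limma the counts were 1026 in vivo, 267 at d0 and 0 at d12 and d21, with 8692 and 8078 tiles at an unadjusted p below 0.05. The d12 count was 55 without d12 BJ1 replicate 1, 52 without d12 BJ1 replicate 2, 254 without d12 JB6 replicate 1 and 208 without d12 JB6 replicate 2. The d21 count was 47 without d21 BJ1 replicate 2, 11 without d21 JB6 replicate 1 and 49 without d21 JB6 replicate 2.

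E14 stem cells were set against the hybrid stem cells to see whether an inbred line kept in another medium shares their state. At d0 E14 had less methylation at 6058 of 143592 tiles and more at 1492, and 2762 were called without d0 E14 replicate 2. Tiles above 80% in the hybrids were lower in E14 in 6.82% of cases. At d21 the tiles between 20% and 80% in the hybrids had a median difference of 19.6 points toward E14, and 19 of 118946 tiles were called. The hybrids pooled here lie apart, with mean levels of 47.4% in BJ1 and 62.6% in JB6 against 66.4% in E14, so the difference is mostly that from BJ1. Cross was not fitted, so this distance also entered the error, and few calls need not mean few differences. Without d21 BJ1 replicate 1 the count was 3, without d21 JB6 replicate 2 it was 2, without d21 E14 replicate 1 it was 1, and without d21 BJ1 replicate 2, d21 E14 replicate 2 or d21 JB6 replicate 1 it was 0 by the logistic test, with 15101, 6530 and 49956 tiles at an unadjusted p below 0.05. Limma called 11970 and edgeR 3260 there. E14 and the hybrids differ in strain background, stem cell medium and coating together, which cannot be separated here.

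Imprinted regions of E14, for which no value per allele exists, were compared by the level over both alleles. E14 stem cells were low at regions that stood near 40% in hybrid stem cells. Impact averaged 6.86% ± 2.91 in E14 at d0 (SD, n = 2) against 37.0% ± 3.44 in the hybrids (n = 4), Zrsr1 10.4% ± 1.51 against 37.9% ± 6.58 and Airn 14.4% ± 1.82 against 40.1% ± 2.68. At d21 E14 stood at 26.8% ± 5.03 for Impact, 42.0% ± 6.83 for Zrsr1 and 47.0% ± 9.02 for Airn. Plagl1 rose in E14 from 23.5% ± 1.26 at d0 to 87.7% ± 6.31 at d21, where the hybrids had 42.7% ± 4.97, and Peg13 from 47.2% ± 3.52 to 93.2% ± 0.245, where the hybrids had 53.6% ± 14. Slc38a4 stayed low in cultures, at 0.355% ± 0.0602 in E14 and 10.5% ± 7.43 in hybrids at d21, against 43.9% ± 6.00 in P0 cortex. Nesp rose in hybrids from 6.15% ± 1.43 at d0 to 47.7% ± 1.14 at d21, next to 42.1% ± 3.97 at P0. Over all covered tiles of the imprinted windows, E14 at d0 averaged 24.7% ± 0.773 and the hybrids 35.5% ± 1.35, with 34 of 134 tiles called lower and 0 higher. Their median difference of -7.54 points was below that of every one of 10000 matched lists, whose median was -0.335 (adjusted p 0.000800 over the 8 lists).

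**Figure D3:**
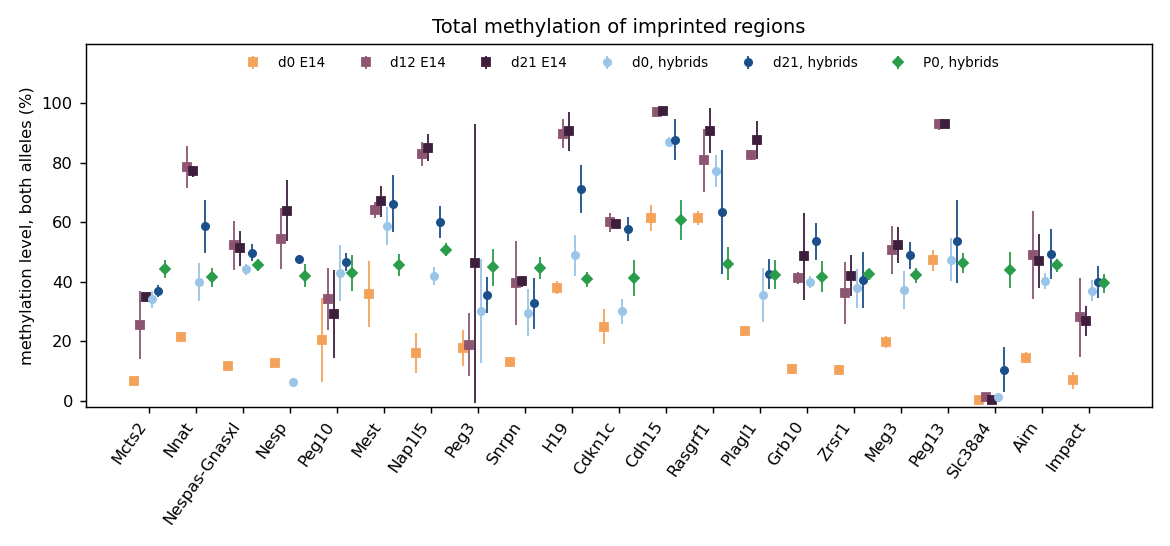
Methylation level over both alleles in percent at 21 imprinted regions whose tiles lie between 30% and 70% in every in vivo sample, as mean with SD bars for E14 at d0, d12 and d21 (n = 2) and hybrids at d0, d21 and P0 (n = 4). E14 at d0 lies below the hybrids and cortex at most regions, with a median of 17.8% against 39.98% in the hybrids at d0.

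The share of allele-assigned reads that came from C57BL/6J was examined along the autosomes of the hybrids. In 25 of 467 segments of 5 Mb, on 9 chromosomes, every hybrid culture lay at least 10 points below every in vivo sample, and in 9 of them below 10%. The segment on chromosome 8 from 110000001 to 115000000 had a median C57BL/6J share of 1.15% in BJ1 cultures and 1.52% in JB6 cultures. In 0 segments did every culture lie at least 10 points above. Kept to tiles with 25% to 75% of calls on each allele in every sample, the parent-of-origin counts were 25 in vivo, 19 at d0, 14 at d12 and 9 at d21.

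**Figure D4:**
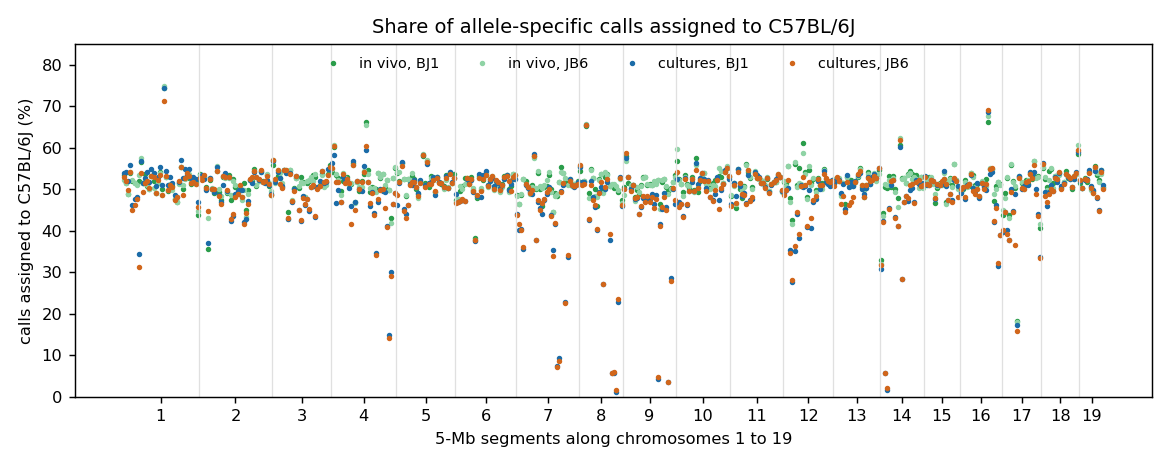
Share of allele-assigned calls from C57BL/6J, in percent, in 5-Mb segments along the autosomes, with a point at the median of the cultures or of the in vivo samples of BJ1 and of JB6. Every culture lies at least 10 points below every in vivo sample in 25 of 467 segments.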

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

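Every test in this part was chosen after values were seen, except the change of E14 against the hybrids, which was planned. Single libraries stood apart from the others of their stage in 19 of 179 groups of mean levels and allele levels, all 19 of them allele levels, where chance marks about 1 in 20 groups, and several of these rest on a level near 0. On the normally unmethylated allele, P0 BJ1 replicate 2 had 23.3% at Dlk1-Meg3-IG (others 7.69% to 9.41%) and 14.8% at H19 (others 4.72% to 6.19%), and d0 BJ1 replicate 1 had 47.6% at H19 (others 24.2% to 26.8%). Nnat stood at 18.5% in d0 JB6 replicate 1 (others 1.3% to 3.08%) and at 0.411% in E13.5 BJ1 replicate 1. Grb10 stood at 4.44% in P0 BJ1 replicate 1. Impact stood at 0.195% in P0 BJ1 replicate 1, 2.39% in d0 BJ1 replicate 2 and 3.29% in d21 BJ1 replicate 2. Peg3 stood at 0.952% in E13.5 JB6 replicate 1, 3.04% in d12 JB6 replicate 2 and 0.299% in d21 BJ1 replicate 2. Inpp5f stood at 0.258% in P0 JB6 replicate 2, Peg12 at 1.82% in E13.5 JB6 replicate 1 and Snrpn at 0.209% in P0 BJ1 replicate 1.

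On the normally methylated allele, Grb10 stood at 72.9% in d21 JB6 replicate 1 (others 86.5% to 88.9%), Inpp5f at 58.9% in d0 JB6 replicate 1 (others 78.0% to 80.4%), Nespas-Gnasxl at 91.2% in P0 BJ1 replicate 1 (others 96.9% to 97.55%) and Zdbf2 at 64.1% in P0 BJ1 replicate 2 (others 74.3% to 74.4%).

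The change from d0 to d21 differed between lines. The interaction of stage and line called 37515 tiles for E14 against the hybrids, but 48 without d21 E14 replicate 2, 1421 without d0 E14 replicate 2, 9826 without d21 E14 replicate 1, 13508 without d21 BJ1 replicate 2 and 23565 without d0 BJ1 replicate 2, and 0 with a replicate block by the logistic test (47273 tiles at an unadjusted p below 0.05, 43733 called by limma without the block). For JB6 against BJ1 it called 52196, 25580 without d0 BJ1 replicate 1 and 29167 without d21 JB6 replicate 2.

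Reads outside the methylation comparisons carried signals too. In 25 segments of 5 Mb the hybrid cultures had few C57BL/6J reads. In E14, the share of reads on chromosome 14 at d0 was 1.14 times that at later stages, and that on chromosome X 1.33 times, where the hybrids had 0.960 and 0.935.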

How the results depend on the processing

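The hybrid lines alone, the interaction of stage and cross, and the replicate block and omissions of the interaction of stage and E14 were added after values were seen. With a threshold of 10 points the tile counts were 54536 for d12 vs d0, 2424 for d21 vs d12, 9919 for P0 vs E13.5, 53920 for d12 vs E13.5, 66846 for d21 vs P0 and 22342 for E14 vs hybrid at d0. With 30 points they were 20325, 19, 1455, 12769, 13561 and 1790, and 15513 for d21 vs d0. With 20 points between alleles, strain tiles numbered 2514 in vivo, 3023 at d0, 855 at d12 and 762 at d21. With at least 20 reads, d21 vs d12 had 200 calls and d21 vs P0 had 22030. Limma called 168 tiles for d21 vs d12 and 11970 for E14 vs hybrid at d21, where edgeR called 3260. For alleles limma called 0 parent-of-origin tiles at d0, d12 and d21 (4499, 4712 and 4718 at an unadjusted p below 0.05, against 3444, 3675 and 3869 by the logistic test), 267 strain tiles at d0 and 0 at d12 and d21 (8692 and 8078). Hybrid lines alone gave 108 calls for d21 vs d12.

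With a replicate in turn left out, counts ranged from 48 to 54318 for the interaction of stage and E14, 25580 to 69133 for that of stage and cross, 204 to 522 for d21 vs d12, 2762 to 10213 for E14 vs hybrid at d0 and 0 to 3 for E14 vs hybrid at d21. Parent-of-origin tiles ranged from 11 to 12 at d12 and 7 to 9 at d21, and strain tiles from 52 to 254 and 11 to 257. The libraries behind the lowest values are named beside each count in the report. A lone sample left in a group is assumed to vary like the other groups.

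The mean level changed by 8.89 points from d0 to d21 over cytosine positions (exact p 0.0370) and by 9.78 to 11.6 without a replicate. From d12 to d21 it changed by -3.90 with each sample's own tiles (exact p 0.00926) and by -3.26 to -2.32 without a replicate.

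At imprinted regions the methylated allele was lower at d21 in 6 over the whole window and 6 by limma, and in 4 to 8 without a replicate, and higher in 2 over the whole window. At d12 it was lower in 0 by limma and 2 to 7 without a replicate, and higher in 2 over the whole window, 0 by limma and 0 to 1 without a replicate. The other allele was higher at d21 in 8 by limma. Impact's other allele reversed without d21 BJ1 replicate 2, to -0.0391 points in a range up to 1.28. Of 812 alternatives for named regions, 687 kept their call, 102 lost it, 22 gained it and 1 reversed, and of 1138 for named tiles 1083 kept it and 55 lost it.

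The replicate block gave 0 calls for the interaction of stage and E14 by the logistic test (47273 tiles at an unadjusted p below 0.05), 1 for E14 vs hybrid at d21 and 6 for the methylated allele lower at d21. Deviations of equal replicate numbers correlated at -0.0716 to 0.154 over tiles, so no pairing by number was seen. No paired analysis was possible for the allele tiles because the term per sample already holds the replicate. The gene lists, with their alternative promoter, were not run.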

Other observations

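BJ1 and JB6 cultures, made from the same parental strains in opposite directions, parted at d21. BJ1 had 11% of tiles above 80% methylation and JB6 53.6%, against 45.3% and 44.5% in P0 cortex of the same crosses. At the gamma protocadherins BJ1 stood at 50.7% and JB6 at 66.4%, against 35.4% and 36.1% at P0. The cell line and the direction of the cross go together here, with 1 line for each, so they stay untested as sources.

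Every test of the 3 patterns below was chosen after the pattern was seen, while the bounds for the read shares of the segments were written before those shares were computed. Splits of tiles and parent-of-origin alleles, and counts for the imprinted windows, had also been seen before their bounds were written.

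The normally unmethylated allele of imprinted regions was methylated in d21 cultures. Reads of the methylated allele assigned to the wrong parent would leave the level over all reads in place. At Zdbf2, H19, Cdkn1c, Cdh15 and Mest every d21 sample lay above every P0 sample over all reads, by at least 3.95 points, which argues against such reads as the whole source there. In the same d21 libraries the unmethylated allele of Peg3, Impact, Snrpn, Zrsr1 and Kcnq1ot1 averaged 0.0749% to 2.18%, which argues against wrong assignment throughout a library. In the other 6 raised regions the samples overlapped in the tiles concerned with the crosses pooled. Within BJ1, every d21 library lay above every P0 library at Nnat (56.2% and 61.7% against 43.0% and 35.9%). The same held at Inpp5f (69.6% and 62.0% against 54.8% and 59.7%) and Meg3 (45.7% and 53.0% against 44.6% and 39.1%). At Dlk1-Meg3-IG they lay below. Within JB6 they lay above at Nnat, Nespas-Gnasxl and Dlk1-Meg3-IG and below at Inpp5f. In the remaining cases they overlapped. These mixed results, from 2 libraries per cross and stage, leave wrong assignment at single regions open there. At Nnat and Grb10, the wider set of tiles between 30% and 70% in vivo was higher over all reads at d21 (58.6% ± 8.96 against 41.5% ± 3.19 at P0, and 53.7% ± 6.20 against 41.6% ± 5.20), but a rise in neighbouring tiles does not exclude wrong assignment in these. Unconverted cytosines reached at most 0.532% in the mitochondrial genome. A rise shared with other loci that are low in cortex cannot be told apart from it: 34.0% of tiles below 20% at P0 rose by 10 points, outside the interval of 38.3% to 85.8% for the regions, while 24.4% at 20 points and 17.8% at 30 points lay inside theirs, and those 2 sizes were added after the 10-point result was seen. Over both alleles the tiles of the imprinted windows rose less than matched lists (3.49 against 18.1 points), but those lists match the level over both alleles and not an allele near 0, so this does not decide it. A gain of methylation in culture may explain the pattern in part, since 5 of the 11 regions were already raised at d0, and it was not tested.

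Segments with few C57BL/6J reads lay in the cultures of both crosses. All reads kept at least 0.969 of their in vivo share in the 9 lowest segments, which argues against a lost copy. JF1 reads rose to at least 1.75 times, with a median of 1.78, which argues against a copy from another strain. JF1 sequence on both copies may therefore be the source, as a hypothesis.

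E14 had low levels at most imprinted regions at d0, below 30% at 16 of 21, and intermediate or high levels at most of them later, with 4 below 30% at d12 and 3 at d21. Slc38a4 stayed low, and Cdh15, Rasgrf1 and Peg13 were not low at d0, with up to 64.5%, 63.2% and 49.7%. Methylation of E14 at d0 was also low in general, with a median difference from the hybrids of -3.82 points over all tiles. In tiles above 80% in the hybrids it was -9.50. The imprinted windows lay lower than matched lists (-7.54 against -0.335 points), but those lists match the level over both alleles and not a methylated allele, so this does not decide it. Unconverted cytosines are argued against by a mitochondrial level of at most 0.327% at d12 and d21. Reads on chromosome 14 were 1.14 times as frequent at d0 as later, so d0 libraries from E14 cells of another chromosome content may have part in it. A gain on 1 of 2 equally read alleles moves the level over both by at most 50 points, but every later E14 sample lay at least 52.0 points above every d0 sample at Nnat, Nap1l5 and Plagl1, which argues against a gain on 1 allele alone there. In the other 18 regions the gap was smaller. Among them, Peg10, Peg3 and Slc38a4 had gaps of -11.5, -10.7 and -0.375 points, so the samples overlapped and no gain was shown there. In the rest a gain on 1 allele and a gain on 2 cannot be told apart, since E14 reads are not split by parent. The medium stays open and untested.

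Among splits of the same samples, only the real one gave as many calls. It was 1 of 60 for d12 vs d0 (32671, highest other 23852), d21 vs d0 (24593, other 1) and d21 vs d12 (301, other 98), where the other splits were drawn at random from a larger number. It was 1 of 35, all that exist, for P0 vs E13.5 (3991, other 4), d12 vs E13.5 (21671, other 0) and d21 vs P0 (33735, other 0). This argues against chance but cannot exclude it, since no share below 1 of 60 or 1 of 35 is possible and the comparisons were not adjusted for each other. The split with 23852 calls exchanged d0 BJ1 replicate 1 and d12 JB6 replicate 2. For parent-of-origin tiles in vivo the real split was the largest of 60 drawn at random (34 without the strain term, highest other 29). The split by strain was not among those drawn and gave 1033, which points to the strain difference of the alleles. The real split is thus not the largest of all, and this test does not exclude chance. For the imprinted regions the in vivo samples chose the tiles, so splits were counted over every tile of the windows. Only the real split gave as many calls at d12 (1 of 35, 24 calls over both alleles of 24 windows, other 2) and d21 (1 of 35, 29 in 25 windows, other 3). This argues against chance within the same limit. In cultures 8 splits are too few for a share under 0.05, with 2 as large: 18 at d0 (other 1426), 9 at d12 (other 500) and 6 at d21 (other 362), and the larger split is that by strain.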
